A study of Mus musculus with 2 samples.

How the data were processed

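Total RNA was extracted with Trizol from CH12F3 cells and from CH12F3 cells labelled Lig4-/-, both grown in RPMI medium with 10% serum, and libraries were made from 5 µg of RNA with an Illumina TruSeq RNA kit, per the labels' protocols. The labels give 1 sample for each line, and each of the 2 value columns of the deposited table was matched to its sample by name. The authors deposited FPKM values, fragment numbers scaled to transcript length and to the mapped fragments of the library, with 2 decimals for 53873 features. The submitters' processing notes name CASAVA and TopHat without versions and the genome build GRCh38. GRCh38 is a human build, whereas 51912 of the deposited features carry mouse Ensembl identifiers, so the build behind the values remained uncertain. The remaining 1961 features carry identifiers of assembled loci, which held 2.26% of the FPKM sum in the CH12F3 library and 3.21% in the library labelled Lig4-/-. The program that made the FPKM values, the annotation release, the strand setting and any treatment of multiply mapped reads are not given in the sources used here. Fragments from overlapping genes and from near-identical copies could have been assigned to either gene, and this bears on single immunoglobulin, histone and MHC genes.

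Gene symbols, chromosomes, transcript lengths and GC contents were taken from GENCODE M21 (mouse GRCm38) by Ensembl identifier, and 51633 identifiers had a symbol there while 279 had none. No coordinate of the deposited table was used. Where identifiers shared a symbol, the one with the highest mean FPKM was kept, which dropped 72 and left 51840 genes. Genes with a mean FPKM over both libraries of at least 1 were called expressed, 11437 in all. The log2 ratio of a gene is log2((FPKM in the library labelled Lig4-/- + 1) / (FPKM in the CH12F3 library + 1)). The pseudocount of 1 FPKM understates the difference of genes with low values. Values were used as the authors deposited them, with no further scaling.

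With 1 library per group there was no test between groups and no p-value. Genes at least 2-fold apart were counted. For each of 35 gene lists, the median log2 ratio of the expressed members was placed among the medians of 10000 random lists of the same size, drawn from expressed genes outside the list and matched on mean expression in 20 bins (seed 1). A list was described as apart where its percentile was under 2.5 or over 97.5, and 4 lists with fewer than 5 expressed members were not scored. Chromosomes were treated in the same way. These percentiles describe the 2 libraries, since genes are not replicates. The groups, lists, thresholds, tests and the rule for named genes were fixed before the data were examined. By that rule the text names Lig4 first, then the 12 expressed genes with the highest and the 12 with the lowest log2 ratio among those at least 2-fold apart (without predicted models, clones, pseudogenes, small RNAs and immunoglobulin or T cell receptor segments), the 2 highest and 2 lowest members of each list with any other member at least 2-fold apart, and the 5 genes with the highest FPKM in each library. Lists of repair genes, p53 targets and B cell genes, and lists that stood apart, were described in full and the others summarised. Other members of a list are named as examples chosen after their values were seen. Some genes that the rule takes in are not reported here.

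Because the log2 ratio followed transcript GC content, a GC adjustment was added after the data were seen. A lowess curve (fraction 0.3) of log2 ratio on the GC content of each gene's longest annotated transcript was subtracted, for the 11404 expressed genes with a GC content (99.7%). Alternatives to the main settings were pseudocounts of 0.1 and 5 FPKM, the overall median log2 ratio set to 0, FPKM rescaled to the same total in both libraries, upper quartile scaling, no expression filter, a mean of at least 5 FPKM, a 4-fold threshold, symbols summed, predicted models left out, list means and unmatched random lists. Added after the data were seen were the GC adjustment, an adjustment for GC content and length, random lists matched on GC content, the inclusion of assembled loci and the removal of genes listed at 0.

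The number of reads per library is not given in the sources used here. It was sought in the FPKM values of short pseudogenes and provisional transcripts, 558 in the CH12F3 library and 647 in the other. Many steps were tried, each on the values that spanned few steps. At the best step 26.5% and 26.0% of these lay within 0.1 of a whole multiple. By chance 20% would for a step fixed beforehand, and more for the best of many. Depth is therefore unknown and no counting interval was computed. Differences among genes near 1 FPKM are therefore less certain than those among abundant genes. An exact 0 can be a failed estimate: mt-Atp6 was listed at 0 in the CH12F3 library, and so no fold is given for a gene listed at 0.

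The steps were tested on simulated data in which 100 genes were changed 4-fold and 100 changed 8-fold, with a GC trend like that of the real comparison, over 11404 genes. Without GC adjustment 91.0% of the 4-fold and 99.0% of the 8-fold changes passed 2-fold in the right direction, and 18.9% of unchanged genes passed it. With the adjustment these shares were 99.0%, 100.0% and 1.37%. The simulated noise was narrower than the spread of the real GC-adjusted log2 ratios (standard deviation 0.73). These shares are therefore not error rates or power for the real comparison. Of 100 simulated lists of 20 genes, 6 were apart with no shift, 85 with a log2 shift of 0.5 and 100 with a shift of 1. These lists were drawn at random from genes with their real GC-adjusted log2 ratios, so the count with no shift was largely set by the thresholds. Lists of unadjusted log2 ratios were not simulated. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.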

Results

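RNA was sequenced from CH12F3 cells, a mouse B cell lymphoma line that carries IgM and is widely used to study switching to IgA, and from CH12F3 cells labelled Lig4-/-. Lig4 encodes DNA ligase IV, the ligase of nonhomologous end joining. Each line was represented by 1 library, so there were no replicates, no spread could be estimated, and every difference below is a description of these 2 libraries. The deposited values were FPKM per gene, which summed to 1020856 in the CH12F3 library and 962435 in the library labelled Lig4-/-. Read depth was not given, and the low values did not reveal it, so no value carries a counting interval. Of 51840 genes, 11437 were expressed, meaning a mean FPKM over both libraries of at least 1, and their median FPKM was 11.1 in the CH12F3 library and 14.6 in the other. Across these genes, which are not independent replicates, Pearson's r of log2(FPKM + 1) was 0.912 and Spearman's rho of FPKM was 0.893.

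The targeted gene came first, as a check of the labels. Lig4 (ENSMUSG00000049717, chromosome 8, positions 9969049 to 9977686 on the minus strand in GENCODE M21 on GRCm38) was listed at 0.13 FPKM in the CH12F3 library and at 0.64 FPKM in the library labelled Lig4-/-. Its log2 ratio, on the scale of FPKM + 1 used throughout, was 0.54, so Lig4 was not lower in the library named for its loss. With a pseudocount of 0.1 FPKM the log2 ratio was 1.69. The adjustment for transcript GC content described below gave -0.57, but its curve was fitted to expressed genes, which Lig4 is not. Among 406 genes of like GC content and level the median log2 ratio was 0.35, and Lig4 stood above it, at percentile 69.6. The turned sign is therefore not read as a lower Lig4. Both FPKM values of Lig4 lay under the expression threshold, and the table gives 1 value per gene, so it does not show whether a deleted part of the transcript was absent. All directions below therefore rest on the label of the library and not on a check by its targeted gene. Of the 14 genes listed as neighbours of Lig4, 7 were expressed and none of these differed 2-fold. They ran from Naxd, at 66.1 and 41.5 FPKM in the CH12F3 library and the library labelled Lig4-/-, to Arglu1, at 5.48 and 11.7 FPKM, with a median log2 ratio of 0.74 (percentile 92.0 among random lists, GC-adjusted -0.33).

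Which genes differed between the parent line and the line labelled Lig4-/- was the question of the series. In the library labelled Lig4-/-, the germinal centre gene Rgs13, the lipid carrier Apoe and the immunoglobulin joining chain Jchain were among the highest relative to CH12F3, while the lactate exporter Slc16a3, the lambda light chain gene Iglc1 and renin (Ren1) were among the lowest. Of the 11437 expressed genes, 2402 were at least 2-fold higher in the library labelled Lig4-/- and 468 at least 2-fold lower, so 83.7% of the 2870 genes beyond 2-fold were higher there. The median log2 ratio of expressed genes was 0.17. With that median set to 0, the split was 1868 higher and 793 lower, or 70.2% higher.

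Transcripts rich in A and T were higher, and transcripts rich in G and C lower, in the library labelled Lig4-/-. Among the 10 deciles of GC content, the median log2 ratio went from 1.36 at a median GC content of 39.8% to -0.41 at 59.6%. In the decile richest in A and T, 68.4% of genes were at least 2-fold higher and 0.789% at least 2-fold lower. In the decile richest in G and C, 1.93% were higher and 10.8% lower. Spearman's rho of log2 ratio with GC content was -0.64 over 11404 expressed genes, -0.66 over 10395 protein-coding genes, -0.41 over 499 long noncoding RNAs and -0.33 over 350 processed pseudogenes. Subtracting a smooth curve on GC content, an adjustment chosen after the data were seen, removed 36.6% of the variance of the log2 ratios and left 657 genes at least 2-fold higher and 682 lower, or 49.1% higher. The curve was fitted to these same log2 ratios and so centres them near 0. The nearly even split was therefore largely fixed by construction. Of the genes with a GC content, 564 of 2397 that were at least 2-fold higher and 284 of 466 that were at least 2-fold lower were so after the adjustment as well. Each scored gene list below is therefore given with its GC-adjusted median.

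**Figure D1:**
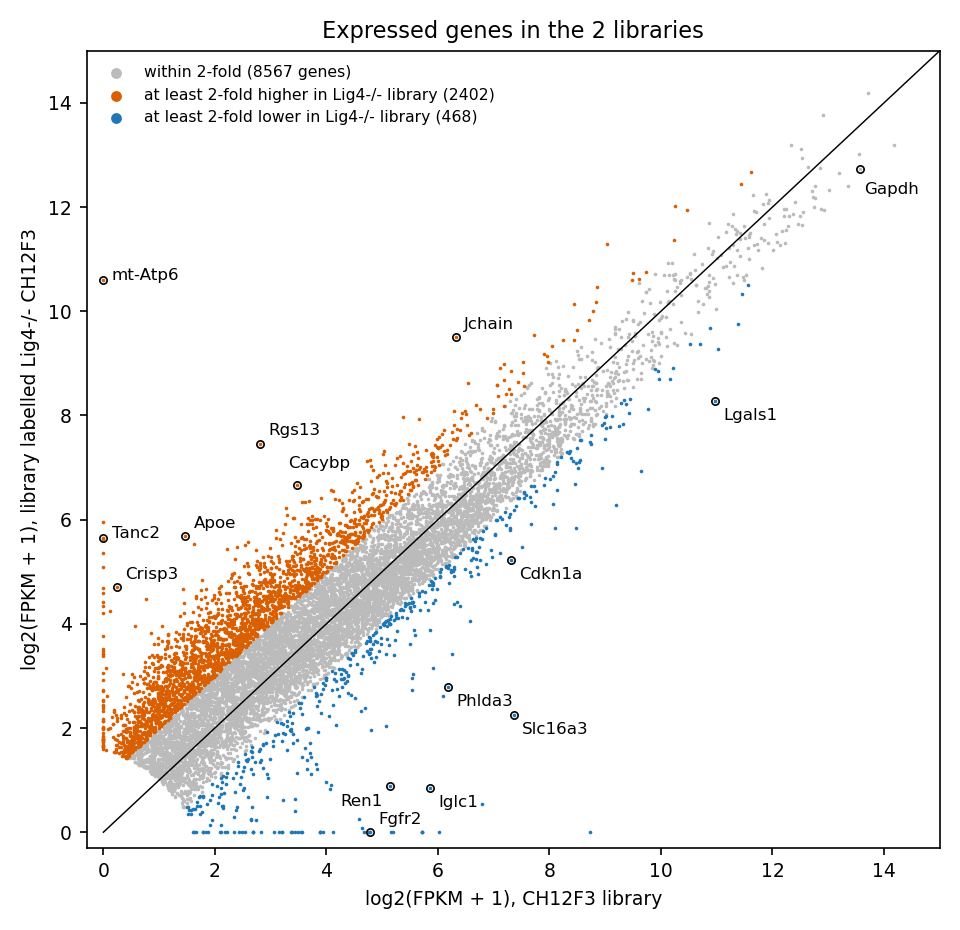
Each point is 1 of 11437 expressed genes, with log2(FPKM + 1) in the CH12F3 library on the x axis and in the library labelled Lig4-/- on the y axis. The 2402 genes at least 2-fold higher in the library labelled Lig4-/- (orange) outnumber the 468 at least 2-fold lower (blue), and points on either axis are genes listed at 0 in a library.

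**Figure D2:**
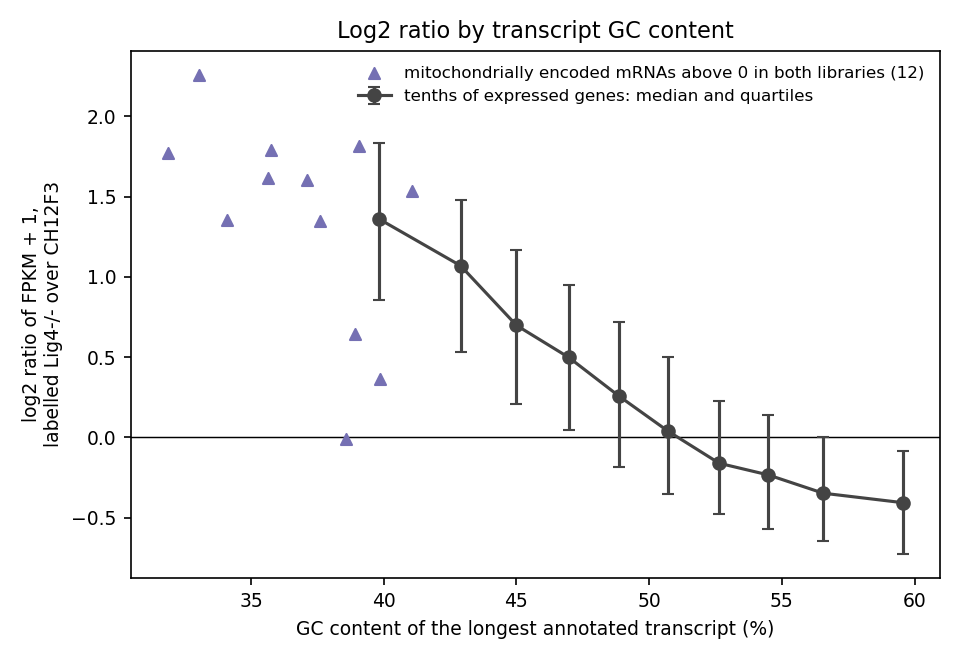
Circles give the median log2 ratio of FPKM + 1 (library labelled Lig4-/- over CH12F3) in each of 10 deciles of transcript GC content, with bars from the lower to the upper quartile, and triangles give single mitochondrially encoded mRNAs. The medians go from 1.36 at 39.8% GC to -0.41 at 59.6% GC.

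Among the 12 highest named genes in the library labelled Lig4-/-, Rgs13, a regulator of G protein signalling in germinal centre B cells, was at 6.0 FPKM in CH12F3 and 175 in that library (log2 ratio 4.65, GC-adjusted 2.93). Crisp3, which encodes a secreted protein, was at 0.18 and 24.98 FPKM (4.46, GC-adjusted 2.93), and Apoe was at 1.76 and 50.5 FPKM (4.22, GC-adjusted 4.61). Jchain, which links IgM and IgA into polymers, was at 78.9 and 722 FPKM (3.18, GC-adjusted 1.72). Cacybp, which encodes a calcyclin-binding protein, was at 10.0 and 100.2 FPKM, Sh3bgrl at 3.63 and 42.4 FPKM, and Efcab7 at 0.49 and 14.6 FPKM, with log2 ratios of 3.20, 3.23 and 3.39 and GC-adjusted values of 1.92, 1.66 and 2.16. The remaining 5 were listed at 0 in the CH12F3 library, so no fold is given. In the library labelled Lig4-/-, mt-Atp6 was at 1557 FPKM, Tanc2 at 48.9, Snhg9 at 24.8, Znrf4 at 23.2 and St6gal2 at 12.6 FPKM. The sequence of mt-Atp6 overlaps that of mt-Atp8, which was at 1214 FPKM in CH12F3, and Snhg9 overlaps a gene on the other strand, so their reads could have been assigned to the partner gene. In all, 50 expressed genes were listed at 0 in the CH12F3 library and 44 in the other, and 14 and 18 of these had at least 10 FPKM in the opposite library.

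Among the 12 lowest named genes, Slc16a3 was at 163 FPKM in CH12F3 and 3.75 in the library labelled Lig4-/- (log2 ratio -5.11, GC-adjusted -4.80). The lambda constant region genes Iglc1, at 57.0 and 0.79 FPKM, and Iglc3, at 67.1 and 5.09 FPKM, had log2 ratios of -5.02 and -3.48 (GC-adjusted -5.19 and -3.93). They belong to a family of closely similar copies, between which reads could have been divided. Ren1, which encodes renin, was at 34.5 and 0.86 FPKM (-4.25, GC-adjusted -4.03). Phlda3, a p53 target that restrains Akt, was at 71.4 and 5.90 FPKM (-3.39, GC-adjusted -2.94), and Mgst2, a microsomal glutathione transferase, at 75.4 and 9.77 FPKM (-2.83, GC-adjusted -3.39). The ATP-gated ion channel P2rx1 (-3.25), Serinc2 (-3.18), the class I histocompatibility gene H2-Q10 (-3.03) and C1qtnf12 (-3.03) followed, with GC-adjusted values of -3.08, -2.83, -2.89 and -2.65. The fibroblast growth factor receptor gene Fgfr2, at 26.4 FPKM in CH12F3, and the phospholipase gene Pla2g4e, at 24.5 FPKM, were listed at 0 in the library labelled Lig4-/-.

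Genes of immunoglobulin chains, ribosomal proteins and the glycolytic enzyme Gapdh were among those with the highest FPKM. In the CH12F3 library they were Rpl13a at 18559, the kappa variable segment Igkv10-96 at 13373, Gapdh at 12143, Rplp1 at 12012 and F630206G17Rik at 10535 FPKM. In the library labelled Lig4-/- they were Igkv10-96 at 18591, the heavy chain variable segment Ighv1-53 at 13919, Rpl13a at 9358, Ighm at 9325 and Igkc at 8871 FPKM. The same heavy and kappa segments led in both libraries. Ighv1-53 held 71.5% of the FPKM of heavy chain variable segments in CH12F3 and 69.7% in the library labelled Lig4-/-, and Igkv10-96 held 99.8% and 99.7% of that of kappa variable segments. The lambda leader differed, with Iglv3 at 20.2 FPKM (50.8% of lambda variable segments) in CH12F3 and Iglv1 at 50.1 FPKM (54.6%) in the library labelled Lig4-/-.

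Gene lists fixed beforehand were then compared with 10000 random lists of like expression. Genes of glycolysis, replication-dependent histones, MHC class I presentation and the interferon response were lower, and mitotic and mitochondrially encoded transcripts higher, in the library labelled Lig4-/- than random lists. These 6 of 31 scored lists lay outside the central 95% of the random medians, where 1.55 would be expected by chance. That expectation takes the members of a list to vary independently. Genes of like function or GC content may not, so it can be too low. After GC adjustment 6 lists lay outside, 4 of them the same. The same 6 lists were apart when the median log2 ratio was set to 0 and under both other scalings. Each of these settings rescales a whole library and so moves a list and its random lists together. This agreement was therefore largely fixed by construction.

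Glycolytic genes were lower as a group, with a median log2 ratio of -0.71 (percentile 0.0), and 18 of 21 lay below 0. Gapdh was at 12143 FPKM in CH12F3 and 6788 in the library labelled Lig4-/-, Eno1 at 5931 and 3229, Aldoa at 4765 and 2527, and Pkm at 4483 and 2472. Slc16a3, Aldoc (3.58 and 0.89 FPKM), Tpi1 (3031 and 1454 FPKM) and hexokinase 1 (Hk1, 102 and 49.4 FPKM) were at least 2-fold lower. The monocarboxylate transporter Slc16a1, at 20.4 and 52.0 FPKM, was the 1 member at least 2-fold higher, and its log2 ratio of 1.31 was 0.30 after GC adjustment. The GC-adjusted median was -0.54 (percentile 1.5), with 3 members 2-fold lower and none higher. Tpi1 (-0.91) and Hk1 (-0.73) were then within 2-fold.

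Replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, were lower too, with 15 of 18 expressed members below 0 and a median of -0.76 (percentile 0.0). Hist1h3c was at 101 FPKM in CH12F3 and 40.8 in the library labelled Lig4-/-, Hist1h4c at 14.8 and 6.13, and Hist1h1e at 3.35 and 0.95. Hist1h2bc went the other way, at 32.5 and 105 FPKM (log2 ratio 1.67, GC-adjusted 1.05). The GC-adjusted median of the list was -0.55 (percentile 0.04). These genes are near-identical copies, so single members are uncertain.

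Of 33 interferon-stimulated genes, 20 were expressed, with a median of -0.46 (percentile 0.01) and 14 members below 0. Oas1a (29.7 and 10.2 FPKM), Usp18 (19.98 and 7.12 FPKM) and Isg15 (109 and 48.4 FPKM) were at least 2-fold lower in the library labelled Lig4-/-, while Gbp3 (5.37 and 13.8 FPKM) and the kinase gene Eif2ak2 (3.04 and 8.20 FPKM) were at least 2-fold higher. After GC adjustment the median was -0.66 (percentile 0.0) with 17 members below 0, and neither Gbp3, at 0.60, nor Eif2ak2, at 0.31, was 2-fold apart.

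MHC class I presentation had a median of -0.71 (percentile 0.08), with 13 of 16 members below 0. The immunoproteasome subunits Psmb8 (641 and 228 FPKM) and Psmb9 (267 and 113 FPKM) and the peptide transporter genes Tap1 (95.3 and 29.3 FPKM) and Tap2 (65.8 and 32.0 FPKM) were at least 2-fold lower in the library labelled Lig4-/-. The class I heavy chain gene H2-D1 was at 2852 and 1622 FPKM, whereas its light chain B2m was at 846 and 1318 FPKM (log2 ratio 0.64, GC-adjusted -0.57). The GC-adjusted median was -0.53 at percentile 2.88, inside the central 95%, with 3 members 2-fold lower and none higher. Tap2, at -0.69, was then within 2-fold. MHC class II presentation, by contrast, had no member 2-fold apart among 13 (median 0.17, percentile 70.9, GC-adjusted 0.25 with none higher and 1 lower, and percentile 98.8 when adjusted for length as well), with H2-Aa at 56.1 and 97.6 FPKM and Cd74 at 1495 and 1570 FPKM. The difference between these 2 lists was not tested.

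Mitotic genes were higher as a group in the library labelled Lig4-/-, with 20 of 21 above 0 and a median of 0.71 (percentile 99.9). The checkpoint kinase gene Bub1 was at 6.31 FPKM in CH12F3 and 37.9 in the other library, the spindle motor Kif11 at 4.66 and 24.3, and topoisomerase II alpha (Top2a) at 63.7 and 192. Plk1, at 88.7 and 79.8 FPKM, was the 1 member below 0. The GC-adjusted median was 0.27 (percentile 99.8), with 2 members, Bub1 and Kif11, still 2-fold higher. Against random lists matched on GC content instead of expression the percentile was 84.7, inside the central range.

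Of 13 mitochondrially encoded mRNAs, 10 were at least 2-fold higher in the library labelled Lig4-/-, with a median of 1.60 (percentile 100). The NADH dehydrogenase subunit mt-Nd3 was at 524 and 2513 FPKM and cytochrome b (mt-Cytb) at 211 and 748. The cytochrome oxidase subunits stood apart from the rest, with mt-Co2 at 740.3 and 735, mt-Co1 at 1834 and 2359, and mt-Co3 at 849 and 1329 FPKM. These transcripts are rich in A and T, with a median GC content of 37.1%, and after GC adjustment the median was -0.02 (percentile 94.8), with mt-Co2 2-fold lower and no member above 0 in both libraries 2-fold higher. Against random lists matched on GC content the percentile was 78.1.

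**Figure D3:**
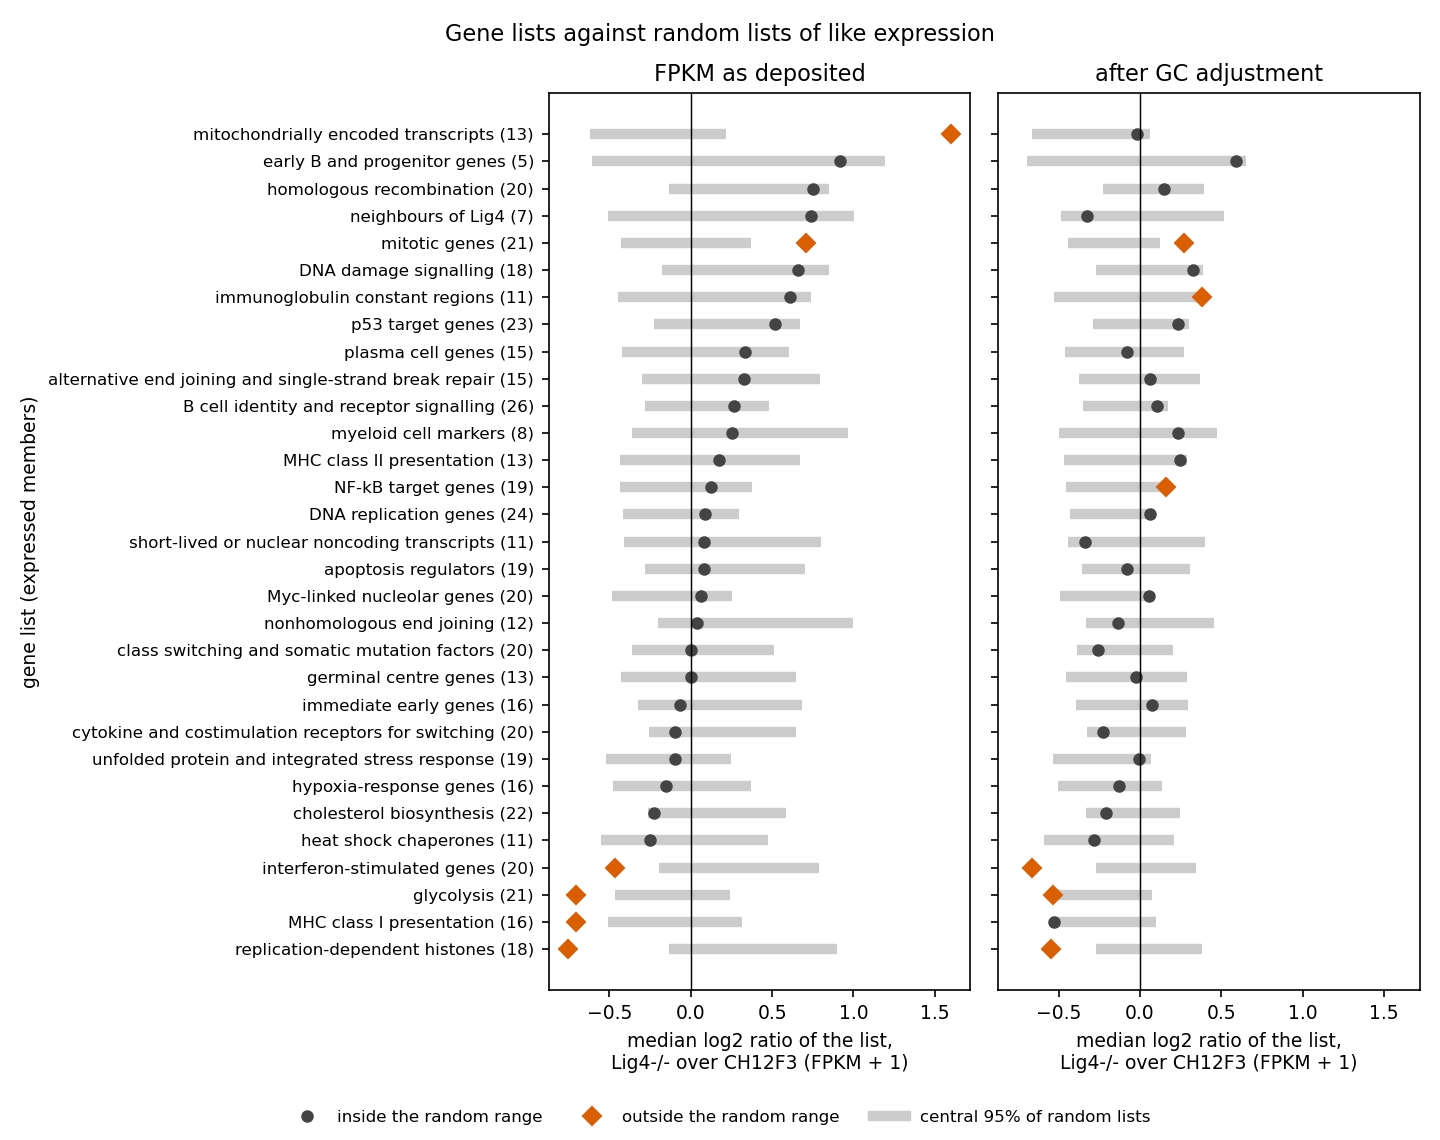
Each row is a gene list with its number of expressed members, symbols mark the median log2 ratio of FPKM + 1 (library labelled Lig4-/- over CH12F3), and grey bars span the central 95% of 10000 random lists of like expression. Diamonds mark the 6 lists outside that range for FPKM as deposited (left) and the 6 after GC adjustment (right), and the mitochondrial median of 1.60 became -0.02.

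The repair lists, which concern the pathway of Lig4 and its alternatives, lay inside the range of random lists matched on expression. Nonhomologous end joining had 12 expressed members with a median of 0.04 (percentile 16.5), which turned to the other side of 0 when the overall median was set to 0 (-0.11), after GC adjustment (-0.13) and for members with a mean of at least 5 FPKM (-0.41). The Ku subunits Xrcc6 (35.0 and 40.8 FPKM) and Xrcc5 (13.98 and 22.5 FPKM), the kinase Prkdc (2.54 and 3.87 FPKM) and the ligase partner Xrcc4 (2.42 and 2.20 FPKM) were within 2-fold. After GC adjustment Xrcc4, at -1.21, was the 1 member 2-fold apart. The Artemis gene Dclre1c was higher in the library labelled Lig4-/- (1.25 and 4.32 FPKM, log2 ratio 1.24, but -0.10 after GC adjustment).

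Among 15 expressed genes of alternative end joining and single-strand break repair, 3 were at least 2-fold higher and none lower, with a median of 0.33 (percentile 69.9, GC-adjusted 0.06 with 1 member higher). The Mre11 complex member Nbn was at 2.96 FPKM in CH12F3 and 22.6 in the library labelled Lig4-/- (log2 ratio 2.58, GC-adjusted 1.76). The end-resection gene Rbbp8, at 1.32 and 7.06 FPKM, and DNA polymerase theta (Polq), at 1.52 and 4.61 FPKM, had log2 ratios of 1.80 and 1.15, and 0.69 and 0.57 after GC adjustment. The ligases Lig1 (124 and 78.9 FPKM) and Lig3 (16.5 and 21.03 FPKM) and Parp1 (241 and 213 FPKM) were within 2-fold.

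Homologous recombination had 9 of 20 members at least 2-fold higher and none lower in the library labelled Lig4-/- (median 0.75, percentile 94.3). The helicase gene Blm was at 6.28 and 24.7 FPKM, and Brca2 at 2.0 and 6.18 FPKM. Against random lists not matched on expression the percentile was 98.2, outside the central range. After GC adjustment the median was 0.15 (percentile 66.6), and of the 9 only Blm, at 1.01, was 2-fold apart. DNA damage signalling had 6 of 18 members at least 2-fold higher and none lower (median 0.66, percentile 90.6, GC-adjusted 0.32 at percentile 94.2 with 2 members 2-fold higher), and its mean instead of its median lay outside the range (percentile 97.52). Rif1, which protects broken ends from resection, was at 0.96 and 8.77 FPKM (log2 ratio 2.32, GC-adjusted 0.95), the checkpoint gene Topbp1 at 9.99 and 34.2 FPKM (1.68, GC-adjusted 1.12), and Trp53, which encodes p53, at 115 and 119 FPKM.

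The p53 target genes lay inside the range of random lists and held members on both sides. Among 23 expressed members, 9 were at least 2-fold higher and 2 at least 2-fold lower in the library labelled Lig4-/-, with a median of 0.52 (percentile 91.7, GC-adjusted 0.23 at percentile 93.8). The cell cycle inhibitor Cdkn1a was at 157 FPKM in CH12F3 and 36.3 in the other library (log2 ratio -2.08, GC-adjusted -1.87), in the same direction as Phlda3. The p53 ubiquitin ligase gene Mdm2, at 21.7 and 82.2 FPKM, and the proapoptotic gene Pmaip1, at 18.6 and 72.9 FPKM, were higher, with log2 ratios of 1.88 and 1.91 and GC-adjusted values of 1.29 and 0.81. After the adjustment 1 member was 2-fold higher and 3 were lower, and among members with a mean of at least 5 FPKM the median was -0.03. Among 19 expressed apoptosis regulators, 5 were at least 2-fold higher and 2 lower (median 0.08, percentile 40.4), and 1 was higher and none lower after GC adjustment (median -0.08). The inhibitor Xiap was at 1.24 and 8.30 FPKM, Bid at 11.6 and 31.0 FPKM and Bcl2l1 at 100.3 and 47.4 FPKM.

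Factors of class switching and somatic mutation were alike in the 2 libraries, with none of 20 members 2-fold apart and a median of 0.00 (percentile 48.1, GC-adjusted -0.26). Ptbp2, at 2.52 and 5.16 FPKM, and Supt5, at 89.0 and 59.0 FPKM, were at the ends of the list. The cytokine and costimulation receptors used to induce switching had 4 of 20 members at least 2-fold higher (median -0.10, percentile 13.8, GC-adjusted -0.23 with 3 higher and 2 lower), including the TGF-beta receptor gene Tgfbr1 (0.64 and 6.71 FPKM) and its antagonist Smad7 (1.43 and 7.37 FPKM). Cd40 was at 342 and 188 FPKM.

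B cell identity and receptor signalling genes had a median of 0.26 (percentile 85.8, GC-adjusted 0.11 with 3 higher and 1 lower), with 5 of 26 members at least 2-fold higher and 1 lower in the library labelled Lig4-/-. The antigen receptor chains Cd79b and Cd79a differed in opposite directions, with Cd79b at 1187 FPKM in CH12F3 and 481 in the other library (log2 ratio -1.30, GC-adjusted -1.11) and Cd79a at 135 and 331 FPKM (1.29, GC-adjusted 1.53). The gene for CD20, Ms4a1, was at 3.28 and 22.7 FPKM. Germinal centre genes had 3 of 13 members at least 2-fold higher, Rgs13, the transcription factor gene Mef2c (7.21 and 34.9 FPKM) and the methyltransferase gene Ezh2 (25.5 and 67.9 FPKM), around a median of 0.00 (percentile 47.7, GC-adjusted -0.02 with 2 higher and 1 lower).

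Plasma cell genes had 5 of 15 members at least 2-fold higher and 1 lower in the library labelled Lig4-/- (median 0.33, percentile 85.2, GC-adjusted -0.08 with 3 higher and none lower). Besides Jchain, these were Cd93 (0.81 and 13.2 FPKM), the elongation factor gene Ell2 (2.95 and 21.7 FPKM), the plasma cell regulator Prdm1 (7.08 and 21.3 FPKM) and Cd28 (7.15 and 16.1 FPKM, log2 ratio 1.07 but -0.14 after GC adjustment). Derl3 was lower, at 8.38 and 3.20 FPKM, and Xbp1 was at 193 and 149.9 FPKM. Immunoglobulin constant regions had 3 of 11 members at least 2-fold higher and 2 lower (median 0.61, percentile 95.3), and lay outside the random range after GC adjustment (0.38, percentile 98.1) and against random lists matched on GC content (percentile 97.9). Their mean had the opposite sign, -0.13, as did their median among members with a mean of at least 5 FPKM, -0.44. Ighm was at 5142 and 9325 FPKM, Igkc at 5818 and 8871 FPKM and Igha at 522 and 331 FPKM. The members 2-fold higher were Ighg1 (0.05 and 5.10 FPKM), Ighd (0.84 and 5.64 FPKM) and Ighg2b (1.95 and 5.45 FPKM).

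Further lists lay inside the random range in the deposited values. NF-kB target genes had 5 of 19 members at least 2-fold higher and 2 lower (median 0.13, percentile 84.2), with Birc3 at 17.6 and 60.5 FPKM and Traf1 at 129 and 51.7 FPKM, and lay outside the range after GC adjustment (0.16, percentile 98.0, 2 higher and 1 lower). Against random lists matched on GC content the NF-kB list lay inside the range (percentile 63.9). Among Myc-linked nucleolar genes 7 of 20 were at least 2-fold higher (median 0.06, percentile 86.5, GC-adjusted 0.06 with 3 higher), including Myc itself, at 36.5 and 90.7 FPKM, and Gnl3, at 12.9 and 63.2 FPKM. DNA replication genes had 4 of 24 members at least 2-fold higher (median 0.09, percentile 85.3, GC-adjusted 0.06 with 1 higher and 2 lower), with cyclin E2 (Ccne2) at 2.35 and 24.1 FPKM and Pcna at 101 and 292 FPKM, while Mcm5 was at 271 and 150.4 FPKM. Cholesterol biosynthesis had 5 of 22 members higher and 3 lower (median -0.23, percentile 4.03, GC-adjusted -0.21 with 1 higher and 2 lower), with Idi1 at 4.95 and 34.8 FPKM and Fdps at 242 and 111 FPKM. It lay outside the range among genes with a mean of at least 5 FPKM (percentile 2.24) and against random lists matched on GC content (percentile 1.07). The medians of the NF-kB, nucleolar and replication lists turned negative when the overall median was set to 0, as did those of the apoptosis, MHC class II, switching factor, germinal centre and noncoding lists. With means in place of medians, the plasma cell (percentile 98.9), replication (98.5) and nucleolar (97.55) lists lay outside the range. The means of the cholesterol list (0.07) and of the hypoxia, heat shock and cytokine receptor lists were above 0, against the sign of their medians.

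The hypoxia-response list had 3 of 16 members at least 2-fold higher and 1 lower (median -0.15, percentile 42.3, GC-adjusted -0.13 with 1 higher and 1 lower), with the prolyl hydroxylase subunit P4ha2 at 46.1 and 7.20 FPKM and Bnip3l at 48.6 and 131 FPKM. Genes of the unfolded protein and integrated stress response had 3 of 19 higher and 3 lower (median -0.10, percentile 65.5, GC-adjusted -0.0068 with none higher and 2 lower), with Dnajc3 at 14.4 and 41.9 FPKM and Trib3 at 61.1 and 21.1 FPKM. Heat shock chaperones (median -0.25, percentile 29.3, GC-adjusted -0.28), immediate early genes (median -0.06, percentile 22.8, GC-adjusted 0.08) and short-lived or nuclear noncoding transcripts (median 0.08, percentile 47.5, GC-adjusted -0.34) also lay inside the range. Malat1, at 2.23 and 13.9 FPKM, was the highest of the last group and Rmrp, at 13.9 and 5.26 FPKM, the lowest.

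Few markers of other cell types were expressed, and some of these differed between the 2 libraries. Of 19 myeloid markers 8 were expressed (median 0.25, percentile 51.5, GC-adjusted 0.23), among them the Fc receptor chain Fcer1g at 266 FPKM in CH12F3 and 77.96 in the library labelled Lig4-/-, and Lyz2 at 0.69 and 4.07 FPKM. Of 20 T and NK cell markers 4 were expressed, with Lck at 15.3 and 20.3 FPKM, Cd4 at 7.42 and 2.64, Cd247 at 0.43 and 2.44, and Cd3d at 0.67 and 1.55. The erythroid genes Hba-a1 (30.5 and 23.6 FPKM) and Hba-a2 (42.1 and 26.4 FPKM) were listed in both libraries, and the only expressed fibroblast or epithelial marker was Vim (239 and 134 FPKM). Early B and progenitor genes had 2 of 5 expressed members at least 2-fold higher, Myb (2.25 and 11.8 FPKM) and Lef1 (6.18 and 15.3 FPKM), with a median of 0.92 (percentile 93.2, GC-adjusted 0.59). None of the 9 sex-linked markers was expressed, and Xist was listed at 0 in both libraries.

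Genes of most chromosomes lay apart from random lists, and those of few did after GC adjustment. Of 20 nuclear chromosomes, 16 lay outside the central 95% of random lists, 9 higher and 7 lower in the library labelled Lig4-/-, with medians from -0.14 on chromosome 15 to 0.57 on chromosome 13. After GC adjustment 4 lay outside, chromosomes 12 (median 0.09, percentile 97.9) and 9 (0.05, percentile 98.4) on the higher side and chromosomes 16 (-0.13, percentile 0.11) and 17 (-0.10, percentile 0.94) on the lower side. Against random lists matched on GC content, chromosomes 12 and 16 were outside as well, 9 (percentile 95.2) and 17 (4.6) were inside, and 7 (0.02), 13 (99.8) and 15 (0.03) were outside. No GC-adjusted chromosome median exceeded 0.09 or lay below -0.13.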

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

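The adjustments for GC content and length, the random lists matched on GC content, the inclusion of assembled loci and the removal of genes listed at 0 were chosen only after the result was seen. No paired analysis was possible because each line has 1 library, and leaving out a library was not possible for the same reason. Of 2870 genes at least 2-fold apart (2402 higher and 468 lower in the library labelled Lig4-/-), 1356 were counted with a pseudocount of 5 FPKM (1104 and 252), 444 at 4-fold (358 and 86), 1339 after GC adjustment (657 higher) and 1287 after adjustment for GC content and length (611 higher), since a larger pseudocount or fold takes in fewer genes by construction and the adjustments remove the GC trend. A mean of at least 5 FPKM left 1589 higher genes because fewer genes were tested, and setting the overall median to 0 gave 793 lower genes. Lig4 passed 2-fold with a pseudocount of 0.1 FPKM, at 1.69, and was at -0.57 after GC adjustment with a curve fitted to expressed genes only. Among named genes, 130 of 227 stayed on their side of 2-fold after GC adjustment (11 of these, within 2-fold throughout, changed sign), 80 came within 2-fold, 6 passed it and a further 11, first beyond 2-fold, reversed: Dclre1c (-0.10), Brip1 (-0.10), Cd28 (-0.14), Nusap1 (-0.14), Dnajb9 (-0.0068), Dnaja1 (-0.14), mt-Nd1 (-0.15), mt-Nd6 (-0.38), mt-Nd4 (-0.021), mt-Atp8 (-0.11) and Dleu2 (-0.29). The count of lists apart stayed between 6 and 7 of those scored except with list means, which gave 10, and the cause was not tested. Chromosomes apart, with the mitochondrial one, went from 17 to 4 after GC adjustment and 5 against lists matched on GC content. Spearman's rho between the libraries was 0.840 for genes with a mean of at least 5 FPKM, the cause of which was not tested. Depth is unknown, which limits genes near 1 FPKM, Lig4 among them.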

Other observations

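The gene groups and single genes of the first paragraphs and most of the tests below were chosen only after the result was seen, the exceptions being the tests of coding-sequence stability, of the level and base composition of Lig4, and of an exchange of the libraries.

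Cohesin and condensin genes, whose products hold sister chromatids together and compact chromosomes, were higher in the library labelled Lig4-/-. Of 20 expressed members 14 were at least 2-fold higher and 1 lower, with a median log2 ratio of 1.88 (percentile 100) and of 0.75 after GC adjustment (percentile 100), when 8 were 2-fold higher and none lower. Stag2 was at 2.40 FPKM in CH12F3 and 27.8 in the library labelled Lig4-/-, the cohesin release factor Wapl at 4.84 and 44.8, Smc4 at 3.97 and 29.8, and Smc2 at 2.52 and 21.7. The group was put together after Smc2, Smc4, Stag2 and Wapl had been seen among the higher genes. Without these 4, the GC-adjusted median of the other 16 was 0.58 (percentile 99.9), with 4 of them 2-fold higher and none lower. The condensin subunit Ncaph2 went the other way, at 279 and 136 FPKM.

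Among TNF receptor genes, 3 were at least 2-fold lower in the library labelled Lig4-/- and kept that size after GC adjustment. Tnfrsf18 (GITR) was at 12.3 and 1.17 FPKM, Tnfrsf4 (OX40) at 24.9 and 4.20 FPKM and Tnfrsf8 (CD30) at 44.2 and 11.3 FPKM, with GC-adjusted log2 ratios of -2.34, -2.08 and -1.69. The 16 expressed members, with Cd40, Fas and Relt, had a median of -0.28 (percentile 1.92) and a GC-adjusted one of -0.40 (percentile 0.74), when Cd40 (-1.14) and Fas (-1.55) were 2-fold lower as well. Without the 3 genes, which had been seen before the group was put together, the median of the other 13 was -0.12 (percentile 12), inside the random range, as was the group limited to symbols in Tnfrsf (percentile 5.6). Cytosolic ribosomal protein genes, 80 in number, had a median of -0.06 (percentile 98.2) and a GC-adjusted one of -0.21 (percentile 94.4). Nuclear-encoded genes of the respiratory chain, 76 in number, had a median of -0.18 (percentile 63.9) and a GC-adjusted one of -0.37 (percentile 12.1), with 3 members 2-fold higher and 2 lower before the adjustment and 1 higher and 10 lower after it. Among genes with a large difference both before and after GC adjustment, the receptor gene Notch1 was at 10.1 FPKM in CH12F3 and 39.7 in the library labelled Lig4-/-, the repressor gene Gfi1b at 0.17 and 3.74, and Tspan13 at 5.69 and 0.18.

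The log2 ratio depended on GC content across the whole table, and more weakly on expression. Among 10 deciles of mean FPKM, its median was 0.35 in the lowest, 0.53 in decile 3 and -0.25 in the highest. After GC adjustment these medians were 0.03, 0.16 and -0.30. Random lists matched on GC content were not matched on expression, so their percentiles also carry this second trend. A difference in mRNA stability read from coding sequence is argued against as the whole cause by long noncoding RNAs, over which Spearman's rho with GC content was -0.41. Over protein-coding genes rho was -0.66, so a part played by coding sequence stays open. Transcript length is argued against by the gap between genes rich in A and T and genes rich in G and C, which was at least 1.37 within each of 4 groups of like length. Recovery of fragments that depends on GC content during library preparation or sequencing may account for the trend, since mitochondrially encoded mRNAs, made by another polymerase, lay around the curve of nuclear genes with a median GC-adjusted log2 ratio of -0.021. Single members were scattered, from -1.43 for mt-Co2 to 0.46 for mt-Nd3 among those above 0 in both libraries. RNA integrity or poly(A) selection, which the length test does not reach and on which the lower replication-dependent histones (GC-adjusted percentile 0.04) may bear, and a difference between the lines themselves were not tested and stay open.

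Interferon-stimulated and MHC class I genes were lower together in the library labelled Lig4-/-. The GC trend as the whole cause is argued against for interferon-stimulated genes, whose GC-adjusted percentile was 0.0, as was their percentile among lists matched on GC content. For MHC class I genes the trend and a difference of their own cannot be told apart, because the adjusted median of -0.53 stood at percentile 2.88, just above a lower end of the random range of -0.54 (before adjustment -0.71 against -0.51), while the unadjusted median stood at 0.01 among lists matched on GC content. Both lists lay below random lists matched on expression, at percentiles of at most 0.08. They were picked out by these same percentiles, which therefore give no separate test of a shift of all highly expressed genes. A general loss of immune transcripts is argued against by MHC class II genes, whose GC-adjusted median was 0.25. A difference between the lines themselves was not tested and stays open, because each line has 1 library.

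Lig4 was not lower in the library labelled Lig4-/-. An unrelated cell clone is argued against by the variable segments, since Ighv1-53 and Igkv10-96 led in both libraries with at least 69.7% of heavy chain and kappa segments, although among the far lower lambda segments (39.6 FPKM in all in CH12F3 and 91.6 in the other) Iglv3 led in CH12F3 and Iglv1 in the other. The ratio of Lig4 stood at percentile 69.6 of 406 genes of like GC content and level, inside their central range of -0.59 to 1.15. With 0.13 FPKM in CH12F3 and a pseudocount of 1 FPKM, a full loss of Lig4 would also fall inside that range. The comparison therefore cannot tell loss from no loss, and whether low level and base composition account for the ratio stays open. An exchange of the 2 libraries cannot be told apart from the labels as given, because 1 library per group leaves no partner to compare. An allele that still gives transcript, which the labels do not describe, was not tested and stays open.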
